A study of Mus musculus with 15 samples.

How the data were processed

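RNA sequencing was carried out by the authors on 15 libraries of mouse splenic B cells, 3 in each of 5 groups, with the replicates of every group lettered A, B and C. The mice were 3-month-old wild-type males immunised with sheep red blood cells (SRBC), a particulate antigen that drives germinal centres in the spleen, and spleens were taken on day 9. Per the labels, B220-positive cells were first enriched magnetically and naive and germinal centre (GC) B cells were then sorted. A further 9 libraries came from naive B cells cultured for 5 days in embryonic stem cell medium with antibody to CD40, with CpG oligonucleotide or with lipopolysaccharide (LPS). The labels give 80 ng/ml of mouse IL-4 with 5 µg/ml of anti-CD40, 2 µM of CpG and 25 µg/ml of LPS, and do not settle whether IL-4 was also given with CpG or LPS. The series text can be read as naive and GC cells both going into culture, and the naive and GC libraries were taken as uncultured from their sample labels. Stimulus and letter were taken from the sample titles as given. The labels do not state which animals the letters stand for, or whether cells were pooled, so p-values measure the spread between libraries whose independence is not known.

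Libraries were made from poly(A)-selected RNA with a strand-aware kit. The authors aligned reads with STAR 2.7.10a to mm10/GRCm38, counted them per gene with featureCounts 2.0.6 and named DESeq2 for their own testing. The handling of strand and of reads that map to several places, and the gene annotation release, are not stated. The deposited table holds counts, whole numbers of reads per gene, for 54838 Ensembl genes, and all 15 of its columns were matched to samples through the library names in the sample descriptions. Symbols, coordinates and biotypes came from GENCODE M21 on GRCm38, which named 54809 of the gene IDs. The other 29 carried at most 0.00872% of any library. Totals ran from 25397624 to 36272197 counts per library. At such totals counting error is small for the abundant genes, and spread between replicates sets the precision. Reads carried no molecular identifiers, so the bounds and intervals given for genes near 0 counts cover counting error only.

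Counts were normalised by the trimmed mean of M values (TMM) and tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups, which left 17144. A quasi-likelihood model (glmQLFit, robust) with 1 mean per group and no block was fitted to all 15 libraries, and 10 comparisons were tested with glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05. The 10 were GC against naive, each activated group against naive, the activated groups against one another, and each activated group against GC. Calls of at least 2-fold were counted beside. Values are CPM, counts scaled by TMM-adjusted library size, given as mean ± SD over n = 3 libraries unless stated, and fold changes are log2. Where every library of a group held 0 counts, the fold is a lower bound against a floor of 3 counts over that group. With 1 to 3 counts the ratio is given with its 95% exact Poisson counting interval, taken from the lower count alone. Shares of counts per library were compared by two-sided exact permutation tests, whose smallest p with 3 against 3 is 0.1.

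Gene lists were 26 for B cell states and pathways and 9 for other cell types, with 635 genes of which 627 were in the table. The first set covered GC B cells, CD40 and light zone genes, plasma cells, follicular B cells, memory B cells, S phase, G2/M, type I interferon response, NF-kB targets, IL-4 and STAT6 response, immunoglobulin constant regions, pluripotency, chromatin regulators, ribosome biogenesis and MYC targets, glycolysis, oxidative phosphorylation, cholesterol synthesis, class II antigen presentation, unfolded protein response, BCL2 family and apoptosis, p53 targets, B cell receptor signalling, Toll-like receptor pathway, cytokines and chemokines, homing and migration receptors, and immediate early and heat shock genes. The second covered T cells, NK cells, myeloid cells, dendritic cells, neutrophils, erythroid cells, megakaryocytes, stroma, and marginal zone and B-1 B cells. Lists were tested with camera (limma 3.58.1), which asks whether a list moves more than the other genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 330 tests, and again with the correlation estimated per list. Members called are given over all genes tested and adjusted over the list alone. A GC signature of 200 genes highest and 200 lowest in GC against naive was tested between the stimuli. Changes in GC and in activated cells, which share the naive libraries, were compared across genes beside 20 simulations in which all groups were redrawn from the naive means.

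Groups, comparisons, tests, lists, the alternatives and the rule for naming genes were fixed before the data were examined. The permutation test of ribosomal protein shares was not in that plan, which named mitochondrial and immunoglobulin shares. The rule names a panel of genes (among them Bcl6, Fas, Mybl1, Prdm1, Irf4, Xbp1, Sdc1, Myc, Cd83, Fcer2a and Ighg1), the 5 largest changes each way (3 against GC) among called genes with at least 20 CPM in the higher group, no overlap between libraries and no immunoglobulin segments or model names, and up to 4 members of each list described, by size of change, with at least 1 CPM. Some genes chosen by this rule are not reported here. Alternatives were DESeq2 size factors, library totals, the DESeq2 1.42.0 Wald test, no low-count filter, a filter at 1 CPM in at least 3 libraries, a fit of only the 6 libraries compared, a block on the replicate letter, immunoglobulin genes left out, and each library left out in turn. List tests were repeated with fry. After the data were seen, fits without the activated libraries of each letter, fits of the 9 activated libraries alone with and without the letter as a block, and contrasts between letters were added.

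The test was tried on simulated data with the dispersions of these libraries and 100 genes changed per fold. It recovered 32% of 2-fold and 84% of 4-fold changes between GC and naive, 25% and 86% between 2 stimuli, and 25% and 76% between CD40-activated and GC cells. With the spread seen between activated libraries of 1 letter given to all simulated libraries, with no letter differences and no block, it recovered 96% of 2-fold and 100% of 4-fold changes between stimuli. These last shares do not give the power of a fit of the real libraries, in which the letters differ.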

Results

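The 15 libraries held 25397624 to 36272197 counts each, and between 11523 and 19320 genes had at least 1 count. None of the 37 mitochondrial genes in the table had a count in any library, so mitochondrial shares are not available. On the first principal components of log2 CPM, which held 41.5% and 22.7% of the variance, GC and activated libraries formed separate clusters, while the naive libraries lay apart from both and from one another. The 9 activated libraries did not separate by stimulus. Each of the 9 had its highest correlation across genes with a library of the same replicate letter and another stimulus. These correlations ran from 0.955 to 0.980 within a letter and from 0.935 to 0.959 within a stimulus. The letter accounted for 49.7% of the variance among the 9 libraries and the stimulus for 17.4%. A share of 25% is expected of each only if neither has an effect. With so large a letter share, a stimulus without effect would also fall under 25%, so 17.4% is not a share below that of no effect. Deviations from the group means correlated between 0.362 and 0.495 for activated libraries of the same letter. Between libraries of the same letter in naive, GC and activated cells they correlated between -0.0696 and 0.0752, so no pairing by letter was seen across these groups. If stimulus name and letter were exchanged in the activated titles, a pairing with activated cells could not show here.

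**Figure D1:**
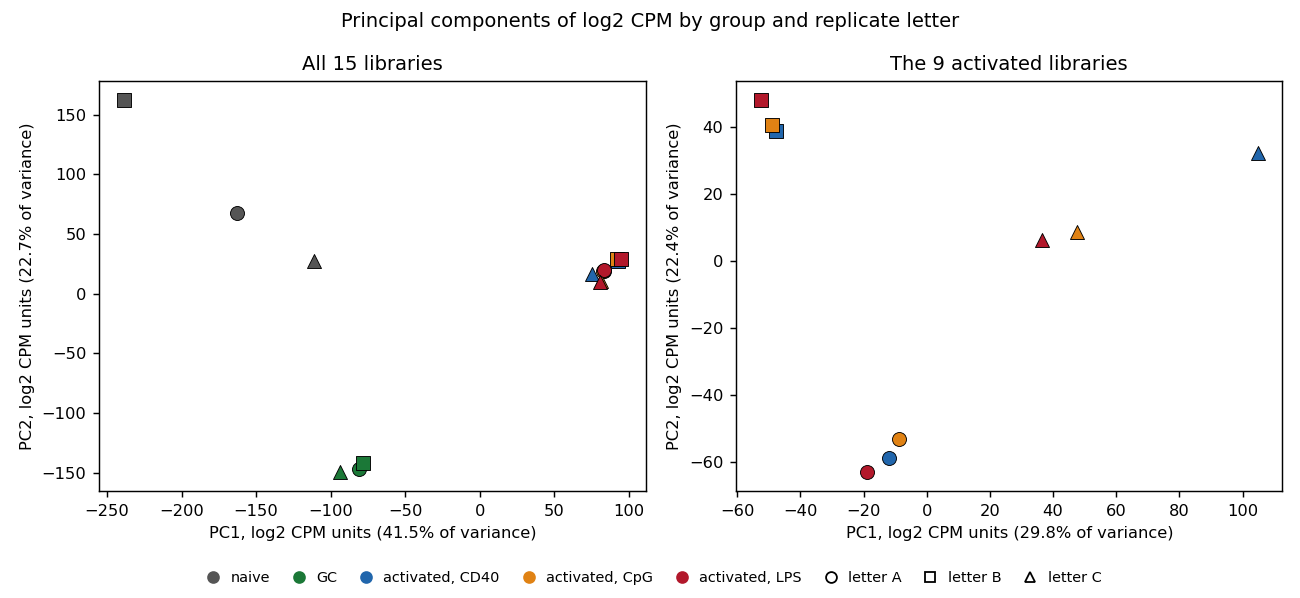
Each point is a library placed by its first and second principal components of log2 CPM, for all 15 libraries on the left and for the 9 activated libraries on the right, with colour for the group and shape for the replicate letter. The first component held 41.5% of the variance on the left and 29.8% on the right, and the activated libraries lie together by letter rather than by stimulus.

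Immunoglobulin genes took 1.55% ± 0.27 of counts in naive cells (mean ± SD, n = 3 here and throughout) and 1.86% ± 0.21 in GC cells. They took 3.50% ± 3.40, 3.81% ± 3.89 and 2.75% ± 2.16 in CD40-, CpG- and LPS-activated cells (exact permutation p between 0.3 and 0.8 over the comparisons). The wide spread followed the letters, at 1.90% ± 0.04 in the activated libraries labelled A, 1.18% ± 0.02 in B and 6.96% ± 1.58 in C. The permutation tests did not pair libraries by letter. Within every letter the share was highest in the library titled CpG and lowest in that titled LPS. With CD40, CpG and LPS it was 1.91%, 1.94% and 1.86% in A, 1.18%, 1.21% and 1.16% in B, and 7.40%, 8.28% and 5.21% in C. Ribosomal protein genes took 11.6% ± 4.80 of counts in naive and 8.46% ± 0.55 in GC cells, against 12.9% ± 2.72, 12.8% ± 2.73 and 13.6% ± 2.31 in activated cells (exact permutation p = 0.1 against GC for each). Haemoglobin transcripts reached 31.4, 265 and 2.91 CPM in naive replicates A, B and C, 5.87 ± 1.79 CPM in GC cells and at most 0.551 CPM in an activated library. Naive replicate B had the fewest genes detected, 11523 against 13920 and 18866 in naive A and C.

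GC B cells, which divide after immunisation, carried known genes of the GC state. Bcl6, the repressor that holds the GC state (ENSMUSG00000022508, GRCm38 chromosome 16, 23965052 to 23988852), rose from 82.0 ± 32.5 CPM in naive to 394 ± 25.8 in GC cells. Its log2 fold change was 2.26 (SE 0.38, adjusted p = 0.000376 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Mybl1, a transcription factor of dividing GC cells, rose from 1.45 ± 1.66 to 462 ± 32.3 CPM (8.32, adjusted p = 1.48e-05). The death receptor gene Fas (ENSMUSG00000024778) rose from 7.61 ± 5.83 to 151 ± 16.4 CPM (4.31, adjusted p = 5.93e-05). The switched heavy chain gene Ighg1 rose from 40.2 ± 34.8 to 1456 ± 119.9 CPM (5.18, adjusted p = 0.000835).

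In all, 3076 genes were higher and 2835 lower in GC than in naive cells, 34.5% of the 17144 tested, and 2203 and 1960 of these changed at least 2-fold. Fitting only the 6 libraries compared gave 4093 calls, against 5911 in the fit of all libraries. Leaving out 1 library at a time gave between 2663 and 4261 higher and between 1849 and 3364 lower genes, with 4261 and 2445 without naive replicate C and 2731 and 1849 without GC replicate A. The largest increases included Cdc25c, a mitotic phosphatase (at least 1287-fold), Pipox, a peroxisomal oxidase (at least 1216-fold), and the transcription factor Ehf (at least 1073-fold), each with no count in naive cells. Gcsam, a GC signalling adaptor, stood at 419 ± 55.1 against 0.0462 ± 0.0801 CPM. The largest decreases included Lgals3, a galectin (21.8 ± 16.7 CPM in naive cells, ratio 1065, counting interval 295 to 8796), the homing receptor Ccr7 (-9.20), the ubiquitin ligase Rnf144a (-8.59) and the cobalamin carrier Tcn2 (-8.57). Irf4, a regulator of activation and plasma cell fate (ENSMUSG00000021356), fell from 197 ± 20.1 to 29.3 ± 5.37 CPM (-2.75, adjusted p = 5.48e-08 in edgeR's quasi-likelihood test). Myc fell from 257 ± 157 to 31.4 ± 6.12 CPM (-3.03, adjusted p = 6.71e-05). Fcer2a, the low-affinity IgE receptor of follicular cells, fell from 983 ± 267 to 64.31 ± 7.499 CPM (-3.93, adjusted p = 0.00826). Prdm1 (adjusted p = 0.325), Xbp1 (0.0752) and Sdc1 (0.504), which mark plasma cells, were not called. Cd83 was lower (-0.89, adjusted p = 0.02), but not without naive replicate B (0.0824) or GC replicate A (0.0841), B (0.0706) or C (0.11).

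Among the gene lists, GC B cell genes had 17 of 20 members higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 4.1e-10). G2/M genes were higher in 36 of 36 members, the same adjusted over the list alone, and S phase genes in 34 of 36, or 36 adjusted over the list alone (1.62e-59 and 1.13e-43). Kif2c, a mitotic motor, stood at 98.9 ± 4.53 against 0.0925 ± 0.160 CPM, and Cdc6, a replication licensing factor, at 87.0 ± 7.31 against 0.497 ± 0.439. Cholesterol synthesis genes were higher in 12 of 20, or 12 higher and 1 lower adjusted over the list alone (7.72e-07), with Cyp51 at 144 ± 11.9 against 19.8 ± 4.18 CPM. Follicular B cell genes were lower in 18 of 23, the same adjusted over the list alone (3.78e-16). Among them were the transcription factor Klf2, at 6.94 ± 2.84 against 1179 ± 426 CPM, and the IgD gene Ighd, at 36.8 ± 1.75 against 3560.3 ± 668. Memory B cell genes had 3 of 15 higher and 8 lower, the same adjusted over the list alone (3.8e-06). Bcl2, a survival gene, fell to 1.68 ± 0.960 from 110.0 ± 13.7 CPM, while Anxa2, an annexin, rose to 464 ± 54.0 from 8.07 ± 4.77. All 6 calls held with an estimated correlation (0.00156 to 0.0207).

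Other lists were called in GC cells with the preset correlation alone. Oxidative phosphorylation genes were higher in 23 of 27, or 24 adjusted over the list alone (2.85e-08, adjusted p = 0.256 with an estimated correlation). Immediate early and heat shock genes had 1 of 18 higher and 12 lower (1.26e-07, adjusted p = 0.155 with an estimated correlation), with Jun at 23.3 ± 9.39 against 983 ± 557 CPM. Homing and migration receptors had 4 of 19 higher and 9 lower (0.000313, adjusted p = 0.106 with an estimated correlation), and S1pr2, which confines cells to the GC, stood at 319 ± 16.0 against 0.920 ± 0.841 CPM. NF-kB targets had 3 of 23 higher and 11 lower (0.0175, adjusted p = 0.363 with an estimated correlation). CD40 and light zone genes had 3 of 25 higher and 15 lower (0.00373, adjusted p = 0.372 with an estimated correlation), with the early response gene Nr4a1 at 21.1 ± 3.64 against 405 ± 333 CPM. Type I interferon genes were lower in 10 of 26 (0.00127, adjusted p = 0.677 with an estimated correlation). B cell receptor signalling genes had 1 of 23 higher and 8 lower (0.0136, adjusted p = 0.233 with an estimated correlation). Adjusted over the list alone, the counts of the last 6 lists were the same.

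Class II antigen presentation genes had 2 of 14 higher and 10 lower in GC cells, or 2 and 12 adjusted over the list alone (0.00152, adjusted p = 0.256 with an estimated correlation). H2-DMb2, which helps load peptides, fell from 1383 ± 196 to 523 ± 68.7 CPM, and the costimulator Cd86 rose from 37.0 ± 4.03 to 177 ± 17.5. Toll-like receptor genes had 2 of 22 higher and 8 lower, or 9 lower adjusted over the list alone (0.00713, adjusted p = 0.133 with an estimated correlation). Tlr7, an endosomal RNA sensor, stood at 0.280 ± 0.134 against 60.7 ± 12.7 CPM.

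The remaining lists were not called in GC against naive cells. Glycolysis genes had 9 of 18 higher and 3 lower (adjusted p = 0.0648), and ribosome biogenesis and MYC targets 12 of 30 and 3 (0.137). Chromatin regulators had 14 of 35 higher and 10 lower (0.0896), with Ezh2, the H3K27 methyltransferase, at 255 ± 16.9 against 19.6 ± 7.74 CPM. Plasma cell genes had 8 of 21 higher and 1 lower (0.44), BCL2 family genes 6 of 17 and 1 (0.407), and unfolded protein response genes 6 of 22 and 4 (0.867). The p53 targets had 2 of 16 higher and 2 lower (0.649), cytokines 5 of 20 and 7 (0.338), and immunoglobulin constant regions 5 of 12 and 1 (0.699). Of the 7 pluripotency genes tested 1 was higher and 2 were lower (0.0768), with Klf4 at 0.547 ± 0.196 against 132 ± 69.4 CPM. IL-4 and STAT6 response genes had 4 of 17 higher and 6 lower (0.129), with the median and the test negative and the mean positive. Adjusted over the list alone, the counts in these lists changed by at most 2 in either direction.

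**Figure D2:**
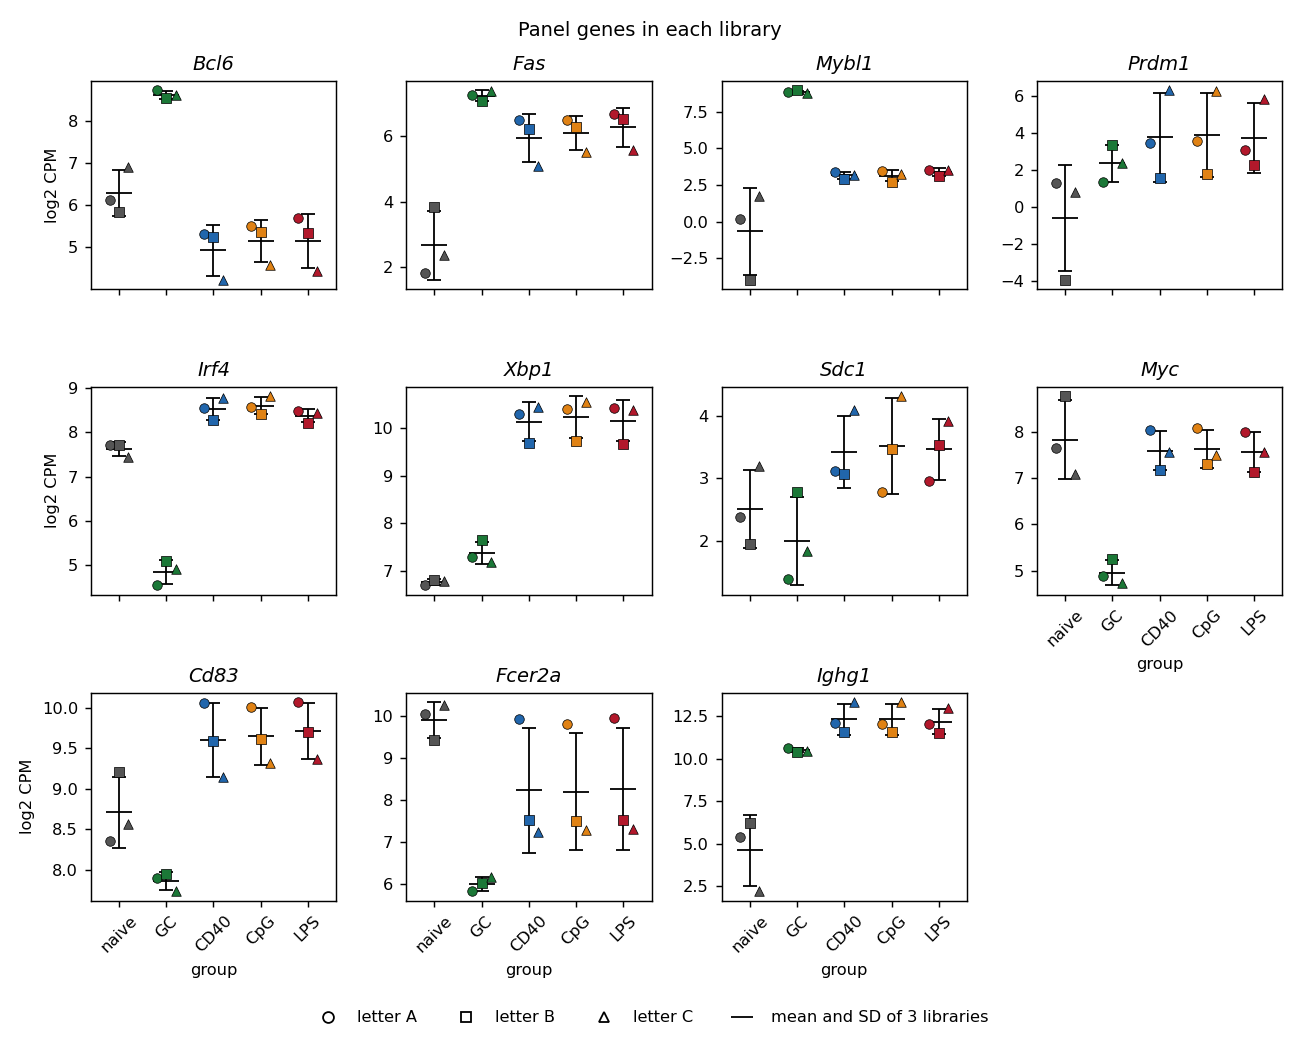
The log2 CPM of panel genes is plotted for each library by group, with the marker for the replicate letter and bars for the mean and SD of 3 libraries. In the activated groups Prdm1 and Fcer2a spread by letter, with Prdm1 at 71.1 CPM in libraries labelled C against 10.2 and 3.63 CPM in A and B.

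Naive cells activated with CD40, CpG or LPS all raised cell cycle genes and lost follicular genes. Ighg1 reached 5871 ± 3894, 5827 ± 3816 and 5071 ± 2655 CPM with CD40, CpG and LPS, against 40.2 ± 34.8 in naive cells (log2 fold changes 7.19, 7.18 and 6.98, adjusted p = 0.000168, 0.000172 and 0.000199 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Xbp1, a regulator of secretion (ENSMUSG00000020484), reached 1162 ± 301, 1242 ± 347 and 1179 ± 317 CPM against 109 ± 4.53 (3.42, 3.51 and 3.44). Irf4 reached 371 ± 63.5, 389 ± 53.9 and 332 ± 32.0 CPM against 197 ± 20.1 (0.91, 0.98 and 0.75), and Fas 66.6 ± 29.1, 71.0 ± 22.8 and 81.1 ± 29.2 CPM against 7.61 ± 5.83 (3.13, 3.22 and 3.42). Bcl6, which rose in GC cells, was lower after activation, at 32.2 ± 11.7, 36.9 ± 11.5 and 37.8 ± 15.2 CPM against 82.0 ± 32.5 (-1.35, -1.15 and -1.12, adjusted p = 0.0124, 0.0276 and 0.031). Its call was lost without naive replicate C (0.0616, 0.13 and 0.141), without activated replicate C (0.0587, 0.131 and 0.136) and, with CpG and LPS, without activated replicate B (0.0669 and 0.083).

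Against naive cells, 3389 genes were higher and 2460 lower with CD40, 3373 and 2395 with CpG, and 3338 and 2441 with LPS. Of these, 2545 and 1465, 2519 and 1439, and 2523 and 1448 changed at least 2-fold. All 3 groups shared 2998 higher and 2062 lower genes, and no gene was called in opposite directions in any pair of them. This agreement is partly built in and does not show that the stimuli act alike. The 3 groups were tested against the same naive libraries, and each mixes letters A, B and C, which set the activated libraries apart more than the stimulus did. Fitting only the 6 libraries compared gave 3005, 3137 and 3349 calls. The median log2 fold change of all genes tested was 0.17, 0.18 and 0.18 with activation and 0.00 in GC cells. Other scalings moved the medians with activation to between 0.14 and 0.24. Leaving out 1 naive library moved them to between 0.125 and 0.412 and that of GC cells to between 0 and 0.243, each highest without naive replicate C. Socs2, a feedback inhibitor of cytokine signalling (ENSMUSG00000020027), was at least 19529, 20752 and 21745-fold higher with CD40, CpG and LPS, and Tnfrsf8, which encodes CD30, at least 10898, 10689 and 10594-fold. The serotonin receptor gene Htr7, the vitamin D receptor gene Vdr and the anchoring filament gene Lad1 were at least 4856-, 4772- and 4278-fold higher with CD40. The largest decreases included the immediate early gene Fosb, from 921 ± 583 CPM in naive cells to 0.605 ± 0.590, 0.802 ± 0.625 and 1.08 ± 0.648 CPM after activation, and with CD40 the related Fos, from 1359 ± 718 to 2.35 ± 1.39. The haemoglobin gene Hbb-bs (at least 1488- and 1525-fold lower with CpG and LPS) came from naive levels of 52.4 ± 73.7 CPM. Naive replicate B held most haemoglobin transcripts, as given above, so this bound rests largely on that library.

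Plasma cell and follicular genes of the panel split by letter within the activated groups. Prdm1, which drives plasma cell formation, stood at 30.7 ± 41.6, 31.1 ± 41.1 and 23.7 ± 29.8 CPM with CD40, CpG and LPS against 1.34 ± 1.21 in naive cells and was not called (adjusted p = 0.0584, 0.0584 and 0.0755 in edgeR's quasi-likelihood test). By letter it stood at 10.2 ± 1.70 CPM in A, 3.63 ± 0.974 in B and 71.1 ± 11.7 in C. Fcer2a was not called either (0.335, 0.304 and 0.348), at 938 ± 48.9 CPM in A, 181 ± 1.20 in B and 153 ± 4.67 in C. With the letter as a block in the 15 libraries Fcer2a was called lower (0.0444, 0.0397 and 0.0474), as Prdm1 was called higher with CpG (0.0469). That block assumes the same letter effect in naive, GC and activated cells. Fcer2a stood at 1048, 690 and 1211 CPM in naive A, B and C, unlike its order in the activated libraries, so the block describes it poorly. Myc (0.492, 0.525 and 0.462) and Sdc1 (0.194, 0.133 and 0.19) were not called.

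A set of 7 lists moved in all 3 activated groups and held with an estimated correlation (adjusted p from 0.00156 to 0.0249). G2/M genes were higher in 36 of 36 members, the same adjusted over the list alone (camera adjusted p = 4.05e-44, 7.23e-44 and 5.81e-43 with CD40, CpG and LPS), with Kif2c at 46.1 ± 5.02 CPM with CD40 against 0.0925 ± 0.160. S phase genes were higher in 32, 30 and 31 of 36, or 33 in each adjusted over the list alone (2.9e-27, 2.22e-26 and 7e-26), with Rrm2, a ribonucleotide reductase subunit, at 258 ± 58.1 with CD40 against 7.21 ± 2.38 CPM. Cholesterol synthesis genes were higher in 17 of 20, or 18 adjusted over the list alone (4.12e-20, 1.24e-19 and 8.45e-19), with Msmo1 at 154 ± 14.7 with CD40 against 13.3 ± 2.92 CPM. IL-4 and STAT6 response genes had 11, 11 and 10 of 17 higher and 1 lower, or 12, 11 and 10 higher adjusted over the list alone (5.99e-05, 5.17e-05 and 9e-05). In contrasts between letters added after the data were seen, 9 of 17 members were higher and 4 lower in A than in B. In B against C, 4 were higher and 5 lower (camera adjusted p = 0.000789 and 0.00266, and 0.107 and 0.118 with an estimated correlation). A against C was not called (0.27). The group values of this list thus pool unlike libraries. Cish, a cytokine feedback gene, stood at 256 ± 39.6, 269 ± 43.5 and 255 ± 47.3 CPM with CD40, CpG and LPS against 1.70 ± 2.77, and the chemokine gene Ccl22 at 607 ± 255, 528 ± 189 and 699.6 ± 197 against 0.0462 ± 0.0801. The p53 targets had 12, 11 and 12 of 16 higher and 1 lower, or 13 higher in each adjusted over the list alone (3.11e-05, 7.74e-05 and 2.64e-05), with the cell cycle inhibitor Cdkn1a at 174 ± 50.9 with CD40 against 0.766 ± 0.939 CPM. Follicular genes were lower in 19 of 23 and higher in 1, or 20, 19 and 20 lower adjusted over the list alone (4.94e-18, 8.05e-18 and 4.13e-18), with complement receptor Cr2 at 4.24 ± 1.16 with CD40 against 835 ± 307 CPM. B cell receptor signalling genes were lower in 19, 17 and 18 of 23, or 19 in each adjusted over the list alone (1.83e-12, 2.19e-12 and 1.5e-12), with the kinase gene Blk at 66.4 ± 28.1 with CD40 against 614 ± 37.2 CPM.

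Metabolic and secretory lists were called higher after activation only with the preset correlation. Glycolysis genes were higher in 15, 16 and 15 of 18, or 16 in each adjusted over the list alone (6.84e-10, 7.87e-11 and 1.88e-09; adjusted p = 0.206, 0.178 and 0.224 with an estimated correlation), with the lactate transporter Slc16a3 at 115 ± 75.5 with CD40 against 0.716 ± 0.809 CPM. Unfolded protein response genes were higher in 15, 14 and 13 of 22, or 16, 16 and 15 adjusted over the list alone (0.00425, 0.00725 and 0.0121, adjusted p = 0.608, 0.628 and 0.638 with an estimated correlation). Oxidative phosphorylation genes were higher in 17, 15 and 16 of 27, or 19, 18 and 17 adjusted over the list alone (0.0027, 0.00659 and 0.00713, adjusted p = 0.622, 0.644 and 0.645 with an estimated correlation). Plasma cell genes were higher in 13, 12 and 12 of 21, or 15 adjusted over the list alone (0.0027, 0.00186 and 0.00342, adjusted p = 0.645, 0.638 and 0.655 with an estimated correlation). Ribosome biogenesis and MYC targets were higher in 14, 12 and 12 of 30, or 15, 12 and 12 adjusted over the list alone (0.0048, 0.0299 and 0.016, adjusted p = 0.577, 0.675 and 0.638 with an estimated correlation). Chromatin regulators were higher in 14, 13 and 13 of 35 and lower in 4, or 15, 14 and 13 higher adjusted over the list alone (0.0288, 0.0306 and 0.044, adjusted p = 0.675, 0.677 and 0.702 with an estimated correlation). BCL2 family genes were higher in 10, 9 and 9 of 17 and lower in 2, or 10 higher adjusted over the list alone (0.00588, 0.00445 and 0.00376, adjusted p = 0.0592, 0.057 and 0.0507 with an estimated correlation), with the survival gene Bcl2l1 at 93.4 ± 12.4 with CD40 against 3.22 ± 3.44 CPM. Cytokine genes were higher in 8 of 20 and lower in 5, 5 and 4, or 10, 8 and 8 higher adjusted over the list alone (0.0202, 0.0314 and 0.0206, adjusted p = 0.0949, 0.132 and 0.106 with an estimated correlation). In contrasts between letters added after the data were seen, 17 of 18 glycolysis genes were lower in A than in B and 16 higher in B than in C. Plasma cell genes were lower in 15 of 20 in A and in 19 of 20 in B than in C, and unfolded protein response genes in 16 and 17 of 22, so the group values of these 3 lists pool unlike libraries. Other lists also split by letter. S phase genes were lower in 28 of 36 in B than in C, and oxidative phosphorylation genes in 19 of 27 in A than in B, with 0 higher in either. Ribosome biogenesis and MYC targets had 19 of 30 lower and 1 higher in A than in C.

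Immediate early and heat shock genes were lower after activation in 12, 13 and 13 of 18 and higher in 2, or 13 lower in each adjusted over the list alone (2.63e-10, 2.99e-10 and 3.22e-10, adjusted p = 0.114, 0.109 and 0.106 with an estimated correlation). Class II genes were lower in 10 of 14 and higher in 2, or 11, 10 and 11 lower adjusted over the list alone (2.64e-05, 3.13e-05 and 2.46e-05, adjusted p = 0.137, 0.138 and 0.136 with an estimated correlation). H2-Ob, which modulates peptide loading, stood at 299.7 ± 82.1 with CD40 against 1672 ± 84.8 CPM. Toll-like receptor genes were lower in 10 of 22, the same adjusted over the list alone (0.00362, 0.00177 and 0.00197, adjusted p = 0.132, 0.106 and 0.106 with an estimated correlation). Memory genes had 4 of 15 higher and 7 lower, or 4, 5 and 4 higher adjusted over the list alone (0.00983, 0.0134 and 0.00732, adjusted p = 0.143, 0.155 and 0.132 with an estimated correlation), with the median positive and the mean and the test negative. Type I interferon genes were lower in 5, 5 and 4 of 26, or 5, 3 and 3 adjusted over the list alone (0.0134, 0.0121 and 0.0175, adjusted p = 0.765, 0.765 and 0.769 with an estimated correlation). In contrasts between letters added after the data were seen, 25 of 26 members were lower in A than in C and in B than in C (median log2 fold changes -3.12 and -2.90), so these group values pool unlike libraries. Homing receptors had 5 of 19 higher and 9, 8 and 8 lower, or 10, 8 and 8 lower adjusted over the list alone, and were not called with CpG (0.0457, 0.0508 and 0.0366, adjusted p = 0.275, 0.312 and 0.267 with an estimated correlation).

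GC B cell genes were not called as a list after activation (camera adjusted p = 0.171, 0.151 and 0.157), with 9, 10 and 10 of 20 members higher and 5, 4 and 6 lower, or 10 higher in each group and 6, 6 and 7 lower adjusted over the list alone. In contrasts between letters added after the data were seen, 11 of 19 members were higher and 3 lower in A than in B. In A against C, 11 were higher and 4 lower, so these group values pool unlike libraries. CD40 and light zone genes had 13, 12 and 11 of 25 higher and 7 lower (0.389, 0.329 and 0.34), and NF-kB targets 9, 8 and 8 of 23 and 4, 3 and 3 (0.497, 0.451 and 0.412). Both lists also split by letter. Of CD40 and light zone genes 6 were higher and 14 lower in A than in B, and 17 higher and 4 lower in B than in C. Of NF-kB targets 5 were higher and 14 lower in A than in B, and 14 higher and 3 lower in B than in C. Immunoglobulin constant regions had 3 of 12 higher and 1 lower (0.954, 0.969 and 0.866), with the test negative and the median and mean positive. Between letters, 9 of 12 were lower and 1 higher in A than in C, and 10 lower and 1 higher in B than in C. The group values of this list pool unlike libraries too. Of 7 pluripotency genes 1 was higher and 2 were lower (0.681, 0.589 and 0.488): Lin28a, an RNA-binding protein gene, stood at 14.4 ± 3.10, 16.9 ± 1.74 and 12.7 ± 0.782 CPM with CD40, CpG and LPS and at 0 counts in naive cells.

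Markers of other cell types were summed per library. Summed T cell markers stood at 18.5 ± 9.01 CPM in naive and 8.52 ± 0.757 in GC cells, and at 538 ± 230.2, 571 ± 208 and 552 ± 238 CPM with CD40, CpG and LPS, of which Thy1 alone made 526, 556 and 537 CPM. The remaining sums are given in the order naive, GC, CD40, CpG and LPS. NK cell markers summed to 16.6, 0.443, 6.73, 8.50 and 8.70 CPM, myeloid markers to 27.2, 16.4, 37.6, 38.9 and 38.9, and neutrophil markers to 19.9, 1.05, 17.1, 13.9 and 17.0. Dendritic cell markers summed to 17.8 ± 14.8, 76.0 ± 9.25, 227 ± 169, 247 ± 175 and 220.0 ± 151 CPM, with 112 to 448 CPM over the activated libraries, and among them Batf3 stood at 18.4 ± 1.86 CPM in A, 190.2 ± 17.5 in B and 63.6 ± 5.31 in C. Erythroid markers summed to 127, 11.2, 3.96, 2.73 and 3.34 CPM, with 18.3 to 319 CPM over the 3 naive libraries, and megakaryocyte markers to 5.33, 1.45, 5.40, 4.45 and 5.64. Stromal markers summed to 309.8, 44.1, 18.9, 19.0 and 20.9 CPM, where Pecam1, which B cells express, stood at 306 CPM in naive cells. None of the 6 of these lists with enough members was called in GC against naive cells (camera adjusted p = 0.879 for T cells, 0.226 for NK cells, 0.547 for myeloid, 0.923 for dendritic, 0.43 for erythroid and 0.698 for stromal markers). After activation erythroid markers were called lower against naive cells with CpG (0.0299, adjusted p = 0.277 with an estimated correlation) and not with CD40 (0.0673) or LPS (0.055), and the other 5 lists were not called. Marginal zone and B-1 markers summed to 1703 ± 254 CPM in naive, 611 ± 85.0 in GC and 259 ± 131, 272 ± 118 and 245 ± 112 CPM in activated cells. They were lower in 8 of 15 members in GC, or 9 adjusted over the list alone (0.0206, adjusted p = 0.345 with an estimated correlation) and in 5 of 15 after activation, or 5, 6 and 6 adjusted over the list alone (0.000234, 0.000589 and 0.000214, adjusted p = 0.144, 0.155 and 0.144 with an estimated correlation).

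**Figure D3:**
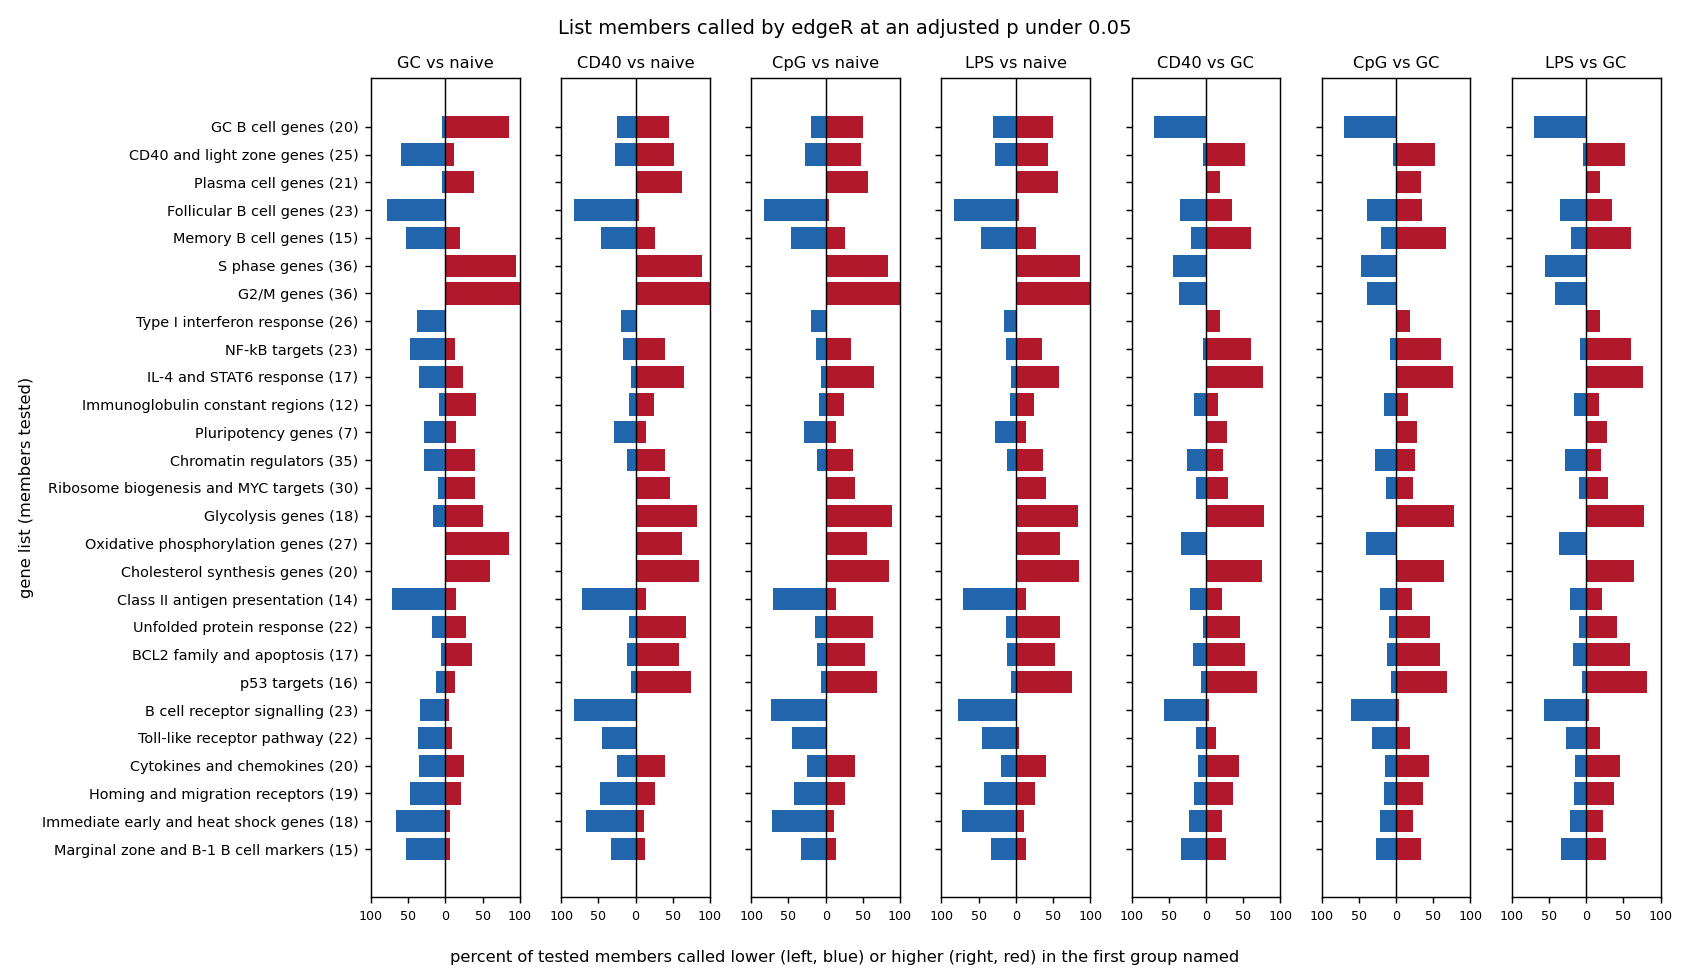
Bars give the percent of each list's tested members called higher (right) or lower (left) at an adjusted p under 0.05 in the first group named, with the number of members tested in brackets. G2/M genes were higher in 36 of 36 members against naive cells in GC and in all 3 activated groups, and GC B cell genes were lower in 14 of 20 in each activated group against GC.

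Between the stimuli no gene was called in the fit of all libraries. edgeR called 0 genes for CD40 against CpG, CD40 against LPS and CpG against LPS, with 92, 115 and 71 genes at an unadjusted p under 0.05, and the DESeq2 Wald test called 1 in each. With the letter as a block in all 15 libraries edgeR again called 0 (79, 115 and 84 at an unadjusted p under 0.05). That block assumes the same letter effect in naive, GC and activated cells, which the libraries did not show. A fit of the 9 activated libraries with the letter as a block, added after the data were seen, called 35, 57 and 53 genes, against 2, 3 and 0 without the block. The 35 genes between CD40 and CpG were 17 higher and 18 lower, the 57 between CD40 and LPS 29 and 28, and the 53 between CpG and LPS 32 and 21. Together these were 99 genes, 9 of them on a gene list. Bcl2a1d, a survival gene of the BCL2 family, stood at 196, 252 and 333 CPM in the libraries titled CD40, CpG and LPS (adjusted p = 0.00155 for CD40 against CpG, 6.08e-10 for CD40 against LPS and 0.000234 for CpG against LPS). Slamf1, an adhesion receptor gene, stood at 12.7, 12.8 and 21.3 CPM, and Tlr9, the receptor for CpG DNA, at 27.6, 27.6 and 18.0 CPM. These 3 genes were chosen after their values were seen. The stimulus is taken from the titles, and because the libraries group by letter it is in doubt whether these genes differ by stimulus.

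Camera called 4 lists between stimuli, and none of the 4 held with an estimated correlation. Ribosome biogenesis and MYC targets (0.000552, adjusted p = 0.448 with an estimated correlation) and erythroid markers (0.00829, adjusted p = 0.159 with an estimated correlation) were higher with CD40 than with CpG. Glycolysis genes (0.00713, adjusted p = 0.638 with an estimated correlation) and marginal zone markers (0.0497, adjusted p = 0.457 with an estimated correlation) were higher with CpG than with LPS. No member of the 4 lists was called in the fit of all libraries. In the blocked fit of the 9 activated libraries Slc2a3, a glycolysis gene, was called for CD40 against CpG (0.0474) and Cad, of the ribosome biogenesis and MYC list, for CD40 against LPS (0.0395), each in another comparison than its list. With the letter as a block in all 15 libraries and the preset correlation, camera called the same 4 and 2 more, glycolysis genes for CD40 against CpG and unfolded protein response genes for CD40 against LPS. An estimated correlation was not tried with the block.

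Activated cells had lower levels of most members of the GC B cell list than GC cells. Rgs13, a GC-specific regulator of G protein signalling, stood at 329 ± 19.3 CPM in GC cells and at 0 counts in every activated library (at least 9782, 9711 and 9954-fold lower with CD40, CpG and LPS, adjusted p = 0.00157, 0.00155 and 0.00157 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Bcl6 (-3.61, -3.41 and -3.38) and Mybl1 (-5.68, -5.69 and -5.45) were lower than in GC cells. Irf4 (3.67, 3.73 and 3.50), Xbp1 (2.79, 2.89 and 2.81), Myc (2.66, 2.69 and 2.64) and Cd83 (1.78, 1.81 and 1.88) were higher. Fas (adjusted p = 0.0916, 0.119 and 0.203), Ighg1 (0.0797, 0.0813 and 0.115) and Prdm1 (0.284, 0.281 and 0.372) were not called.

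Against GC cells, 2733 genes were higher and 2132 lower with CD40, 2805 and 2153 with CpG, and 2714 and 2095 with LPS, and all 3 groups shared 2449 higher and 1773 lower genes. Here too the 3 groups share their reference libraries and mix the same letters, so part of this agreement is built in. Changes of at least 2-fold numbered 2130 and 1181, 2208 and 1160, and 2136 and 1153. Fitting only the 6 libraries compared gave 6519, 6836 and 6880 calls, against 4865, 4958 and 4809 in the fit of all libraries. The largest increases were Htr7 (at least 5048-, 5070- and 5603-fold), Vdr (at least 4961, 5106 and 4114-fold) and Pros1, which encodes protein S (at least 4614, 4682 and 4436-fold). Beside Rgs13, the largest decreases included Tox2, a transcriptional regulator (at least 896- and 890-fold with CD40 and CpG), and with LPS its relative Tox (at least 1087-fold) and Nxpe2 (at least 1569-fold).

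Against GC cells 6 lists were called in all 3 activated groups and held with an estimated correlation (0.00246 to 0.0371). GC B cell genes were lower in 14 of 20 members, or 16, 15 and 15 adjusted over the list alone (camera adjusted p = 9.55e-09, 1.59e-08 and 1.31e-08), with Gcsam at 1.13 ± 1.05 CPM with CD40 against 419 ± 55.1. IL-4 and STAT6 response genes were higher in 13 of 17, or 14, 15 and 13 adjusted over the list alone (1.4e-11, 1.4e-11 and 2.18e-11), with the IgE gene Ighe at 1643 ± 1281 with CD40 against 17.2 ± 1.21 CPM. Ighe stood at 2304, 210 and 2569 CPM in the activated libraries labelled A, B and C, so its group values pool unlike libraries. The p53 targets had 11, 11 and 13 of 16 higher and 1 lower, or 13 higher in each adjusted over the list alone (1.44e-07, 6.46e-07 and 1.05e-07), with the stress sensor gene Sesn2 at 116 ± 20.8 with CD40 against 7.94 ± 1.51 CPM. Cholesterol synthesis genes were higher in 15, 13 and 13 of 20, or 16, 16 and 15 adjusted over the list alone (6.88e-06, 2.29e-05 and 3.39e-05), with Mvd at 129.9 ± 31.5 with CD40 against 23.1 ± 2.79 CPM. B cell receptor signalling genes were lower in 13, 14 and 13 of 23 and higher in 1, or 14 lower in each adjusted over the list alone (2.63e-06, 4.51e-06 and 1.94e-06), with the kinase gene Syk at 174 ± 80.8 with CD40 against 817 ± 117 CPM. Cytokine genes were higher in 9 of 20 and lower in 2, 3 and 3, the same adjusted over the list alone (0.000212, 0.00067 and 0.000266), with the growth factor gene Vegfa at 114 ± 16.8 with CD40 against 0.0364 ± 0.0630 CPM.

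Cell cycle lists were lower than in GC cells. G2/M genes were lower in 13, 14 and 15 of 36, or 15 in each adjusted over the list alone (7.49e-07, 2.48e-07 and 9.89e-08, adjusted p = 0.0592, 0.0507 and 0.0441 with an estimated correlation), with the chromatin protein gene Hmgb2 at 454 ± 49.5 with CD40 against 1853 ± 117 CPM. S phase genes were lower in 16, 17 and 20 of 36, or 19, 20 and 21 adjusted over the list alone (3.8e-06, 6.2e-07 and 4.76e-07, adjusted p = 0.226, 0.177 and 0.174 with an estimated correlation). CD40 and light zone genes were higher in 13 of 25 and lower in 1, or 13, 15 and 14 higher adjusted over the list alone (6.95e-06, 4.28e-06 and 3.84e-06, adjusted p = 0.142, 0.133 and 0.133 with an estimated correlation), with the cytokine subunit gene Ebi3 at 60.5 ± 11.0 with CD40 against 2.51 ± 0.379 CPM. NF-kB targets were higher in 14 of 23 and lower in 1, 2 and 2, or 15 higher in each adjusted over the list alone (7.78e-05, 5.99e-05 and 3.76e-05, adjusted p = 0.133, 0.133 and 0.124 with an estimated correlation). Glycolysis genes were higher in 14 of 18, or 15, 16 and 15 adjusted over the list alone (2.81e-06, 5.78e-07 and 5.68e-06, adjusted p = 0.331, 0.296 and 0.345 with an estimated correlation), with the hexokinase gene Hk2 at 84.7 ± 17.2 with CD40 against 15.9 ± 1.10 CPM. Memory genes were higher in 9, 10 and 9 of 15 and lower in 3, or 9, 10 and 10 higher adjusted over the list alone (0.0118, 0.00713 and 0.0174, adjusted p = 0.142, 0.124 and 0.155 with an estimated correlation), with the transcription factor gene Zeb2 at 63.9 ± 21.8 with CD40 against 1.96 ± 0.412 CPM.

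Oxidative phosphorylation genes were lower than in GC cells in 9, 11 and 10 of 27, or 10, 15 and 14 adjusted over the list alone (0.00586, 0.00211 and 0.00191, adjusted p = 0.638, 0.608 and 0.605 with an estimated correlation). Unfolded protein response genes were higher in 10, 10 and 9 of 22, or 13, 13 and 12 adjusted over the list alone (0.00187, 0.00425 and 0.00641, adjusted p = 0.555, 0.605 and 0.622 with an estimated correlation). BCL2 family genes were higher in 9, 10 and 10 of 17, or 10 in each adjusted over the list alone (0.0428, 0.0357 and 0.0299, adjusted p = 0.137, 0.133 and 0.124 with an estimated correlation). Plasma cell genes were higher in 4, 7 and 4 of 21, the same adjusted over the list alone (0.0299, 0.022 and 0.0366, adjusted p = 0.762, 0.752 and 0.765 with an estimated correlation). Pluripotency genes were called higher with CD40 (0.0497, adjusted p = 0.235 with an estimated correlation) and not with CpG (0.0723) or LPS (0.114). Homing receptors were called higher with CpG (0.0397, adjusted p = 0.297 with an estimated correlation) and not with CD40 (0.0545) or LPS (0.0691). Neither list was called between the stimuli, so these calls do not show a difference between them. Follicular genes (0.811, 0.727 and 0.825), with 8 of 23 higher and 8, 9 and 8 lower, were not called. Also not called were type I interferon (0.457, 0.442 and 0.39), chromatin (0.934, 0.971 and 0.954), ribosome biogenesis (0.289, 0.663 and 0.49), class II (0.532, 0.61 and 0.53), Toll-like receptor (0.969, 0.855 and 0.862), immediate early (0.344, 0.418 and 0.39) and immunoglobulin constant region genes (0.92, 0.934 and 0.813). Marginal zone and B-1 markers were not called (0.226, 0.369 and 0.225), with the test negative and the median and mean positive, and neither were the lists of other cell types.

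Which stimulus leaves cells nearest to GC cells was asked with the 200 genes highest and the 200 lowest in GC against naive cells. Between stimuli the median log2 fold change of the GC-high genes was 0.02 for CD40 against CpG (camera adjusted p = 0.0978), 0.02 for CD40 against LPS (0.363) and -0.01 for CpG against LPS (0.279). For the GC-low genes it was -0.04 (0.127), 0.01 (0.279) and 0.06 (0.00603, adjusted p = 0.297 with an estimated correlation). The stimuli were taken from the titles. If stimulus name and letter were exchanged, each titled group would mix all the stimuli, and medians near 0 would follow whatever the stimuli did. The question of which stimulus leaves cells nearest to GC cells is therefore not settled.

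Across genes, which are not independent replicates, log2 fold changes against naive in GC cells and in CD40-, CpG- and LPS-activated cells correlated at r = 0.545, 0.545 and 0.547. As these comparisons share the naive libraries, simulations without any change gave r = 0.498 on average and 0.520 at most. The covariance was 1.98, 1.97 and 1.98, against 0.299 on average and 0.322 at most in the simulations. Over the 9053 genes with a mean of at least 10 CPM, r was 0.561, 0.554 and 0.560 and the covariance 1.48, 1.46 and 1.48. For genes at that level the simulations gave 0.495 and 0.0652 on average. The simulations gave every group the same spread per gene, pooled over all libraries. Naive libraries varied more than that of GC cells, with correlations of 0.865 to 0.933 against 0.962 to 0.973 between libraries of a group. The simulated r and covariance may therefore be too low, and the small excess in r cannot be read as shared change. Genes higher in both GC and activated cells numbered 1808, 1786 and 1802, where independent calls would give 608, 605 and 599. Genes lower in both numbered 1288, 1271 and 1310, where independent calls would give 407, 396 and 404, and opposite calls numbered 313, 311 and 306. In all 3 activated groups, 1665 genes were higher and 1157 lower as in GC cells, 181 were higher where GC was lower, and 84 lower where GC was higher. Part of the shared calls can come from the shared naive libraries, which were too few to divide between the comparisons.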

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

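Fits without all activated libraries of a letter, fits of the 9 activated libraries alone, with and without the letter as a block, and letter contrasts were chosen only after results were seen; the other alternatives were fixed beforehand. Of the changes from the first fit, fitting only the 6 libraries lowered the calls against naive cells. They fell to 3005 with CD40, 3137 with CpG and 3349 with LPS, and from 5911 to 4093 in GC cells. Against GC cells the same fits raised the calls from 4865, 4958 and 4809 to 6519, 6836 and 6880. The first fit shares its estimate of the spread over all groups, so the counts against naive and against GC depend on that sharing. Between stimuli, where edgeR called 0, no low-count filter gave 1 gene for CpG against LPS (Klhdc1), and the DESeq2 Wald test gave 1 for CD40 against CpG, 1 for CD40 against LPS (both Gm6787) and 1 for CpG against LPS (Klhdc1). The replicate block in the 9 activated libraries gave 35, 57 and 53 genes, and no block in the 9 activated libraries 2 for CD40 against CpG and 3 for CD40 against LPS. Leaving out the activated libraries lettered A gave 3262, 3305 and 3216 calls for CD40, CpG and LPS against GC, from 4865, 4958 and 4809. With the replicate block in all 15 libraries, which assumes the same letter effect in every group, calls went to 6199 in GC against naive and stayed at 0 between stimuli. Of 330 gene list tests 136 were called, against 46 with estimated correlation and 216 with fry mixed. In the GC signature, 500 genes per direction gave an adjusted p of 0.029 for GC high genes in CD40 against CpG, and estimated correlation gave 0.297 for GC low genes in CpG against LPS. Cdh5, an endothelial gene near 1 CPM that was not called in the first fit, changed sign without naive replicate C, to 7.47 with CD40 and 7.67 with CpG against naive cells, and stayed at -1.18 and -0.99 without naive replicate B.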

Other observations

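Letter contrasts and the tests of few starting molecules and of red blood cell RNA were chosen only after results were seen, the former with the letters of the activated libraries already known to group them. With the stimulus as a block, 2611 genes were higher and 2298 lower in libraries labelled A than in B, 1910 and 1793 in A than in C, and 2747 and 2745 in B than in C (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 20 plasma cell genes tested, 15 were lower and 1 higher in A than in C, 19 were lower in B than in C, and 15 were higher and 1 lower in A than in B (camera adjusted p = 8.72e-15, 7.74e-48 and 4.97e-11, and 0.19, 0.09 and 0.217 with an estimated correlation). Jchain, which links secreted antibody, stood at 89.1 ± 22.1 CPM in A, 17.8 ± 0.992 in B and 2154 ± 648 in C, the IgM gene Ighm at 3866 ± 295, 3696 ± 289 and 23658 ± 6898, and Prdm1 at 10.2 ± 1.70, 3.63 ± 0.974 and 71.1 ± 11.7. Fcer2a was highest in A (938 ± 48.9 CPM, against 181 ± 1.20 in B and 153 ± 4.67 in C). Il2rb, a cytokine receptor chain, stood at 6.55 ± 0.856 CPM in A, 139 ± 16.2 in B and 101 ± 19.9 in C, and Ighe at 2304 ± 229, 210.2 ± 13.1 and 2569 ± 191. Type I interferon genes were lower in 25 of 26 members in A than in C and in B than in C (camera adjusted p = 6.27e-32 and 2.9e-29, and 0.09 for both with an estimated correlation), and were not called in A against B (0.494), with 4 higher and 5 lower. Glycolysis genes were lower in 17 of 18 members and higher in 1 in A than in B, and higher in 16 and lower in 1 in B than in C (2.4e-20 and 1.89e-19, and 0.0529 for both with an estimated correlation). They were not called in A against C (0.99).

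The activated libraries group by letter and not by stimulus, and some candidate explanations were tested. If the stimulus name and the letter were exchanged in the sample titles, genes that differ between stimulus names within a letter would mark animals, and would match differences among the GC libraries. Over 88 such genes the best matching gave a mean correlation of 0.714, above all 10000 random gene lists (highest 0.604, percentile 100). This met the prediction set for an exchange, and failed that set for titles as given without a lasting stimulus difference. The random lists were matched on expression and not on differing between stimulus names. The percentile therefore does not show how often such a match arises without an exchange. Titles as given with a lasting stimulus difference were not tested. Naive libraries showed no such match. There the matching best in GC libraries gave -0.225, the lowest of the 6, and the best was a different one at 0.236, which 10000 random lists did not set apart (percentile 86.5). The naive check weighs little against an exchange. Naive libraries correlated with one another at 0.865 to 0.933, against 0.962 to 0.973 among GC libraries. The labels also do not state that a letter stands for the same animals in naive and GC libraries. GC content or transcript length bias is excluded as the whole cause of the differences between A and C, since 89.8% of those calls stayed. The correction was not tried for A against B or B against C, so it does not speak for letter B. Animals that differ between letters stay open. The same-letter correlation in GC libraries was -0.129, under the bound set beforehand, but that bound was wrong, because it assumed that a letter stands for the same animals in GC and activated libraries, which the labels do not state.

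Naive replicate B stands apart from naive A and C, and no biological explanation was tested. It had no count for 299 genes at 5 CPM or more in naive A and C, against 1 and 2 such genes for naive A and naive C. Red blood cell RNA is excluded as the whole cause, since added RNA dilutes other transcripts and does not remove them. Transcript length or GC content bias is excluded as the whole cause, as a spread of 0.729 remained after a trend was removed, against 0.361 between naive A and C. Few starting molecules stay open and cannot be told apart from other losses of transcripts, because the 299 genes largely restate that naive B had the fewest genes detected, and its differences from naive A and C also followed transcript length and GC content (Spearman correlations of -0.298 and 0.346).

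Regrouping the 6 libraries of a comparison in all 10 ways gives too few splits for a share under 0.05. For GC against naive the real split called 4093 genes and the highest other 0, so 1 split of 10 called as many. For CD40, CpG and LPS against naive the real splits called 3005, 3137 and 3349 genes and the highest other 0, again 1 of 10 each. For CD40, CpG and LPS against GC the real splits called 6519, 6836 and 6880 and the highest other 0, 1 of 10 each. Between stimuli every split called 0, so all 10 of 10 called as many in each of the 3 comparisons.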
